A study of Arabidopsis thaliana with 2 samples.

How the data were processed

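Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole Arabidopsis thaliana seedlings of the Ws background, with an antiserum raised against full-length LHY, a MYB-type transcription factor of the circadian clock. Per the labels, seedlings were 2 weeks old and were collected 2 h after dawn, then cross-linked with 1% formaldehyde for 10 min. Chromatin was fragmented to 100 to 1000 bp, and 9 immunoprecipitated samples were pooled into each library. There was 1 library from wild-type plants and 1 from lhy-21, a line in which LHY is knocked out, so no result has a replicate check. All p-values describe how this region list is spread over genes or base pairs. They do not measure variation between plants, and intervals cover counting error only.

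The deposited values are 1 list of regions, each with a start, an end and a score. Per the submitters' processing notes, Bowtie, MACS2 2.0.10.09132012 and the TAIR9 genome were used. Per the labels' design text, a region is one where reads from the wild-type library were over-represented against the lhy-21 library, so the list holds regions of 1 direction only. The score of each region is the authors' value. Its scale is not given in the sources used here, so it served only to rank, filter and describe regions within this list. Filters on reads, the peak caller's threshold and the number of reads per library are likewise not given in the sources used here, and read depth and signal tracks were not analysed here. A region missing from the list therefore shows no absence of binding.

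The centre of a region is the midpoint between its start and end, since a summit was not used here. Positions are TAIR9, counted from 1. Gene positions and symbols came from a RefSeq gene table of assembly TAIR10.1, which holds 27444 nuclear protein-coding genes, of which 10374 have a symbol other than their locus name. The nuclear chromosome sequences of TAIR9 and TAIR10 are the same. The match was also checked on the data, by moving all centres along the chromosomes. In each of 24 segments of 5 Mb with at least 100 regions, the share of centres inside genes was lowest without a shift, against shifts of 500 and 1000 bp to either side. Gene models may still differ between the annotations, so no gene coordinates are given.

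The tests were fixed before the data were examined, with classes and windows set by the transcription start site. The gene table used here gives no strand, exons or sequence. Each window was therefore taken from 1000 bp outside to 200 bp inside either end of a gene, and a region on the promoter side was not told apart from one on the downstream side. A centre in the windows of several genes was counted for each of them. Many of the regions named in the Results were shared in this way, such as at PRR3, LUX, PRR9, CRY2, RD29B, COR15A and CBF2. Sharing is stated there only for some genes, and which gene a shared region belongs to was not determined. Location had 3 classes, which are inside protein-coding genes, outside but within 1000 bp of a gene end, and farther away. Promoter, UTR, exon and intron classes were not separated, and the planned search for 12 sequence motifs, among them the evening element, was left out.

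Shares of centres per class were compared with shares of base pairs by two-sided exact binomial tests and with 1000 circular shifts of all centres along each chromosome. The fifth of 100 kb bins with the fewest genes was tested by the two-sided exact binomial test only, without circular shifts. For 16 gene lists of 251 genes, all found in the gene table, the share of members with a centre in their window was compared with all other protein-coding genes by a two-sided Fisher's exact test. The lists cover evening clock genes, morning and day clock genes, flowering time, light signalling, abscisic acid metabolism, abscisic acid signalling, cold and dehydration response, the light harvesting complex, chlorophyll synthesis, starch metabolism, phenylpropanoids and flavonoids, gibberellin, ethylene, jasmonate, housekeeping reference genes and the RuBisCO small subunit. For lists with at least 3 such members, the mean percentile of each member's highest score was compared with that of other genes with a region, by a two-sided permutation test with 100000 resamples. Benjamini-Hochberg adjustment ran over the classes or the lists, with 0.05 as the threshold, and intervals are exact 95% (Clopper-Pearson). The rule for named genes took all clock genes, the 4 members of every other list with the highest scores, and the 10 genes with the highest scores of all, where a tie makes 11.

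Alternatives were smaller sets of strong regions (the 1000 strongest, the strongest 10% and those above the median), windows of 500 and 3000 bp, overlap of the whole region in place of its centre, assignment to the nearest gene end only, the nearest in place of the strongest region, merging of regions within 200 bp, and circular shifts. Other backgrounds were added after the data were seen. The result of 1 symbol family is not reported here. On simulated data, the list test recovered 94% of lists with 90% of members carrying a region against 40% of 27444 genes, and 72% of lists of 9 genes. It called 2.5% of lists with no difference. Simulated genes carried regions independently and lists were random, so these rates do not cover shared regions or lists of genes with a symbol. The test of strength recovered 100% of simulated lists of 12 genes whose scores were 4 times higher, and called 2.5% of those without a change. The location test called 4% of sets of random centres. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, bedtools 2.31.1 and matplotlib 3.10.9 were used.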

Results

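Regions over-represented in wild-type against lhy-21 chromatin were examined to ask which genes lie at sites of LHY occupancy 2 h after dawn. The list held 14718 regions on the 5 nuclear chromosomes. Their median width was 285 bp, with quartiles of 170 and 495 bp and a range from 103 to 3023 bp, and together they covered 5498 kb. The authors' score ran from 2.00 to 213, with a median of 10.1 and quartiles of 5.70 and 22.3. Density ranged from 117 regions per Mb on chromosome 3 to 131 on chromosome 1. Wider regions had higher scores, with a Spearman correlation of 0.73 across regions, which are not independent replicates. Merging regions within 200 bp of each other left 12816.

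The strongest region, with a score of 213, lay on chromosome 5 from 22935900 to 22936940 (TAIR9). Its centre was 114 bp outside an end of SYNC1, a cytosolic asparaginyl-tRNA synthetase, and 336 bp outside AT5G56670. The next, on chromosome 4 from 15185053 to 15186223, scored 179 and fell in the windows of AT4G31270, AT4G31280 and AT4G31290. A region on chromosome 3 from 11252272 to 11252961 scored 177 and was centred 191 bp outside PHS1, the plastidial alpha-glucan phosphorylase. It was also in the window of AT3G29310. The other genes with the highest scores were AT4G24790 and ECIP1, which encodes a partner of the ethylene regulator EIN2, with a shared region at 173, and OEP16-1, a plastid envelope channel, and CXIP4, with a shared region at 168. Among the 7 strongest regions, those ranked 4 and 6 had no protein-coding gene end in reach. The former, on chromosome 3 from 3592839 to 3593729, scored 173 and was centred inside AT3G11420, and the latter, on chromosome 4 from 17249591 to 17250386, scored 171 and was centred 1527 bp from AT4G36550.

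Regions gathered at the ends of genes. Of the centres, 48.1% (95% interval 47.3 to 48.9) lay outside genes within 1000 bp of a gene end, where 20.4% of base pairs lie, a 2.36-fold excess. Inside protein-coding genes there were 34.8% (34.0 to 35.6) against 54.1% of base pairs, or 0.643-fold. Farther from any gene there were 17.1% (16.5 to 17.7) against 25.5%, or 0.671-fold. Circular shifts, used as a two-sided permutation test, gave folds of 2.36, 0.642 and 0.674 for these classes, with p = 0.002 for the 2 former, the smallest that 1000 shifts can give, and p = 0.012 for the last (adjusted p = 0.003, 0.003 and 0.012). The density of centres was highest in the 100 bp just outside a gene end, at 3.83-fold, and was 3.04-fold in the 100 bp just inside. Of the 5123 centres inside genes, 54.9% (53.5 to 56.3) lay within 200 bp of an end, a zone with 14.7% of the base pairs inside genes. The median distance of outside centres from the nearest gene end was 393 bp. Within the class farther from any gene, centres were not depleted throughout. From 1000 to 1100 bp outside a gene end the fold was 1.57, and from 1900 to 2000 bp it was 1.32. Beyond 3000 bp there were 2.69% of centres against 14.3% of base pairs, or 0.188-fold.

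**Figure D1:**
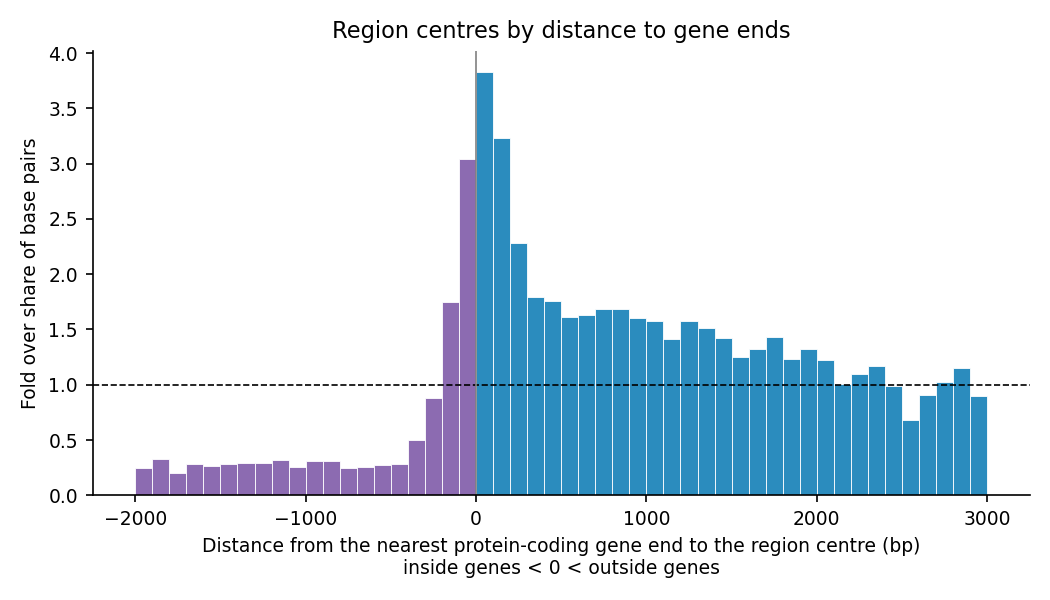
Density of region centres by distance from the nearest end of a protein-coding gene, in steps of 100 bp, as the share of regions divided by the share of base pairs (fold, vertical axis). Purple bars are inside genes, blue bars outside and the dashed line is a fold of 1; the density is highest just outside the gene end, at 3.83-fold.

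Gene-poor parts of the chromosomes held few regions. The fifth of 100 kb bins with the fewest genes, 239 bins with at most 17 genes each, held 4.12% (3.81 to 4.46) of centres, against 20.0% of base pairs and 6.14% of genes. Among the 1000 strongest regions the share was 4.90% (two-sided exact binomial p = 4.65e-43). This test treats regions as independent, and circular shifts were not run for the bins, so the p-value may be far too small. For the class farther from any gene, the exact binomial test gave p = 4.57e-131 where circular shifts gave p = 0.012. The share of centres inside genes was 34.9% (32.5 to 37.4) in the weakest 10% of regions and 33.4% (31.0 to 35.9) in the strongest 10%.

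All 9 evening clock genes had a region. The highest scores were at PRR3, a pseudo-response regulator (93.8), at ELF3 (91.2), a member of the evening complex, and at BOA (85.2), a close relative of LUX. LUX, also of the evening complex, had 67.1 and PRR5 had 60.4. Scores of 46.8 and 37.7 were found at GI and FKF1, which act together in the photoperiodic control of flowering, 31.0 at ELF4, the remaining member of the evening complex, and 15.4 at TOC1, a repressor of the morning genes. The ELF3 region lay on chromosome 2 from 11058617 to 11059383, with its centre 56 bp inside a gene end, and the PRR5 region on chromosome 5 from 8358190 to 8360373, 735 bp outside. The TOC1 region, on chromosome 5 from 24674338 to 24675321, was centred 134 bp outside the gene and ranked 5220 of 14718. Its score was close to the median of 13.7 over all genes with a region.

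Of the morning and day clock genes, 12 of 14 had a region. LHY itself had a region on chromosome 1 from 37749 to 38264, centred 135 bp outside the gene, with a score of 55.9. The region was shared with the neighbouring gene UMAMIT28. Because lhy-21 is altered at LHY, the comparison cannot tell binding there from an effect of the mutation on local reads. CCA1, the closest relative of LHY, had 14.0. Among the pseudo-response regulators, PRR9 had 81.2 (chromosome 2, 19231620 to 19233072) and PRR7 had 34.5. The MYB-like REVEILLE genes RVE7, RVE2, RVE6 and RVE4 had 66.8, 60.1, 29.7 and 9.79. The clock-regulated LNK2, LNK3, LNK4 and LNK1 had 24.1, 17.4, 16.6 and 12.6. RVE8 and RVE1 had none within 1000 bp, and with a window of 3000 bp their highest scores were 4.49 and 102.

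Across the genome, 11200 of 27444 protein-coding genes (40.8%) had a region in their window. Evening clock genes stood at 100% (66.4 to 100) against 40.8% of other genes (two-sided Fisher's exact test, adjusted p = 0.000836), and morning and day clock genes at 85.7% (57.2 to 98.2; exact adjusted p = 0.00280). The 2 lists were not tested against each other for the presence of regions. Their scores were compared by mean rank, after the data were seen, and ranked higher in the evening list (two-sided exact permutation p = 0.041). The medians were 60.4 over 9 evening genes and 26.9 over 12 morning and day genes.

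Genes of photosynthesis and of carbohydrate stores were rich in regions. All 18 genes of the light harvesting complex, the antenna proteins of both photosystems, had one (exact adjusted p = 1.56e-06), led by LHCB1.4 and LHCB1.5, which share a region scored 104, LHCB1.3 (95.3) and LHCB2.1 (77.6). In starch metabolism 16 of 19 genes had a region (84.2%, exact adjusted p = 0.000579), with PHS1 at 177, the starch synthase SS4 at 146 and the branching enzymes SBE2.2 and SBE2.1 at 121 and 93.5. Each of these named starch regions was also in the window of another gene. In chlorophyll synthesis 9 of 11 genes had a region (exact adjusted p = 0.015), among them HEMA1 (57.8), of an early step of the pathway, the cyclase subunit gene CRD1 (51.5), the protochlorophyllide reductase gene PORB (49.2) and CAO (27.4). The 4 RuBisCO small subunit genes all had a region (exact adjusted p = 0.037), at 26.9 for RBCS1A, 9.39 for the region shared by RBCS1B and RBCS2B, and 7.88 for RBCS3B. This RuBisCO call rests on 3 distinct regions and was lost with the shared region counted once (exact adjusted p = 0.091), against genes matched on non-coding base pairs (permutation adjusted p = 0.053), with windows of 500 bp (exact 0.14) and 3000 bp (0.17) and with the nearest gene end only (0.13). The chlorophyll synthesis call was lost with a window of 3000 bp (exact adjusted p = 0.23) and above the median score (0.051).

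Among stress and hormone genes, 20 of 22 cold and dehydration response genes had a region (90.9%, exact adjusted p = 7.50e-06). These included the dehydration marker RD29B (105), the chloroplast-protecting COR15A (91.9), CBF2, a master transcription factor of cold acclimation (90.1), and COR27 (75.8). Of 29 abscisic acid signalling genes 23 had one (79.3%, exact adjusted p = 0.000129), among them the receptor genes PYL7 (138) and PYL5 (72.7), the kinase gene SNRK2.3 (74.3) and ABF1 (70.3). The PYL7 region was also in the window of another gene. All 16 jasmonate genes of the list had a region (exact adjusted p = 4.71e-06), with 60.7 and 59.1 at the repressors JAZ2 and JAZ9, 57.3 at the lipoxygenase LOX3 and 43.1 at AOS, of jasmonate synthesis. The list holds only some JAZ genes. The symbol stem JAZ in the gene table had a region at 6 of 10 genes (exact adjusted p over 172 symbol families = 0.90). That stem had 0 genes among the 1000 strongest regions, whereas JAZ2 and JAZ9 both had one. It therefore leaves out at least these genes and is not a count of all JAZ genes. Whether the full share depends on which members were listed was not determined. Gibberellin genes counted 10 of 13 (exact adjusted p = 0.015), with the receptors GID1C and GID1A at 51.0 and 49.8, the growth repressor GAI at 16.9 and the receptor GID1B at 11.9.

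Light signalling genes counted 19 of 25 (76.0%, exact adjusted p = 0.00161), with the blue light receptor CRY2 (83.9), the growth-promoting PIF4 (57.1), the repressor of light responses SPA1 (38.1) and ELIP1 (33.6). Flowering time genes counted 11 of 14 (78.6%, exact adjusted p = 0.00949). Scores were 109 and 75.9 at CDF1 and CDF5, repressors of CONSTANS, and 81.4 and 43.5 at the floral repressors FLC and SVP. CO, FT and TSF, named after their values were seen, had no region within 1000 bp. With a window of 3000 bp the highest scores were 38.2 for CO, equal to that of its neighbour COL1, and 16.1 for FT, and TSF had none. In the strongest 10% of regions the calls for flowering time (exact adjusted p = 0.079), light signalling (0.75), jasmonate (0.10) and gibberellin (0.25) were lost.

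The other 4 lists did not pass the test with this window and all regions, but each passed in other settings. Abscisic acid metabolism had 7 of 14 (50.0%, exact adjusted p = 0.59), with CYP707A2, of abscisic acid breakdown, at 45.2, ABA1 at 32.1 and the carotenoid-cleaving enzymes NCED5 and NCED4 at 28.2 and 16.9. Ethylene had 12 of 21 (exact adjusted p = 0.19), led by the negative regulator CTR1 (69.9) and by EBF1 (52.6), which marks EIN3 for degradation. ACS2 and ETR2 followed at 29.1 and 17.3. Phenylpropanoids and flavonoids had 8 of 12 (exact adjusted p = 0.10), where chalcone synthase, CHS, scored 128, FLS1 46.5, F3H 14.0 and CHI 12.5. Housekeeping reference genes had 7 of 10 (exact adjusted p = 0.12), with GAPC1 at 57.3, EF1A at 50.7, UBQ10 at 48.5 and PP2AA3 at 38.9. Housekeeping genes passed in the strongest 10% of regions (exact adjusted p = 0.047) and with windows of 500 bp (0.027) and 3000 bp (0.014). With the nearest gene end only, abscisic acid metabolism (exact adjusted p = 0.010), ethylene (0.0064) and phenylpropanoids (0.0071) passed. Ethylene (exact adjusted p = 0.018) and phenylpropanoids (0.0058) also passed with 3000 bp, and phenylpropanoids with any overlap (0.011).

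**Figure D2:**
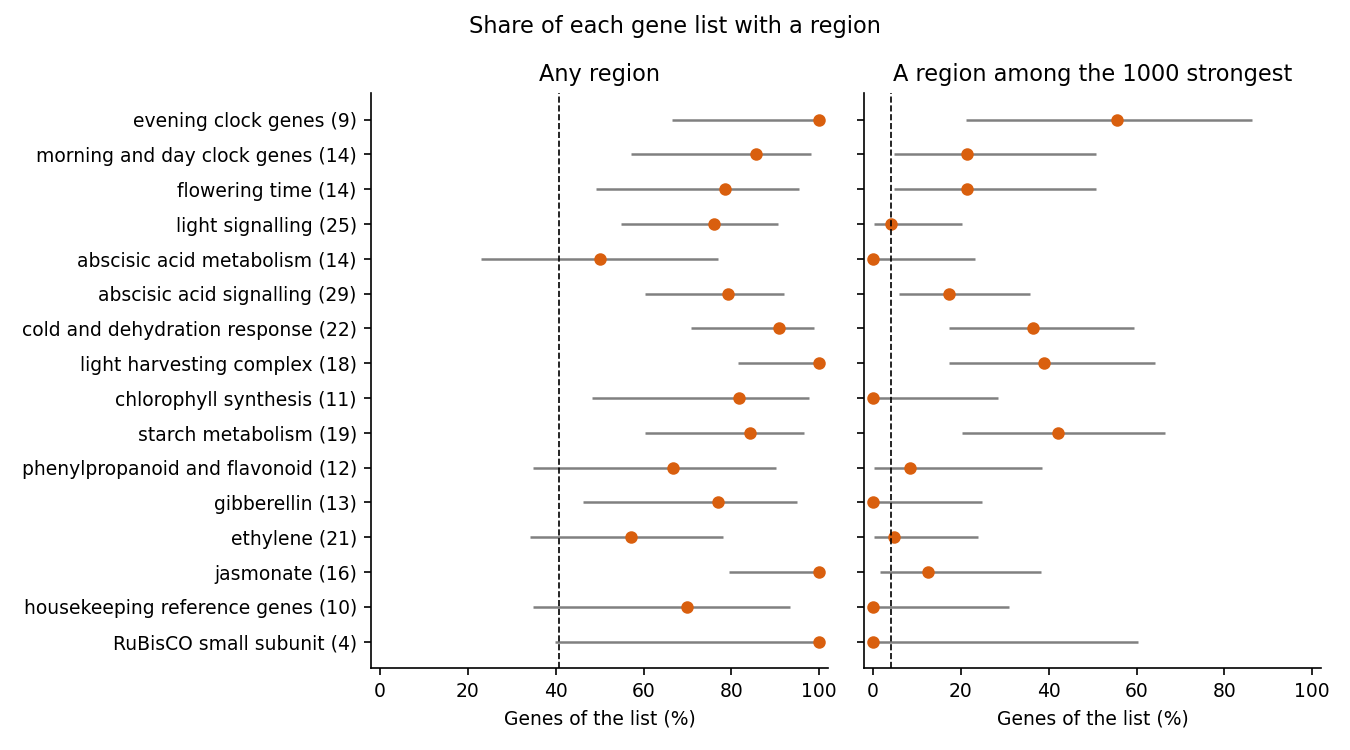
Share of each gene list (number of members in parentheses) with any region in its window, left, and with 1 of the 1000 strongest regions, right, in percent. Points are shares, grey lines exact 95% intervals covering counting error only and dashed lines the median share of genes outside the lists; 12 of 16 lists passed the test for any region and 7 for the strongest regions.

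With only the 1000 strongest regions, which scored at least 58.0 and reached 1126 genes (4.1%), 7 of the 16 lists passed the test in place of 12. Starch metabolism had 8 of 19 (42.1%, exact adjusted p = 6.32e-06), cold and dehydration response 8 of 22 (36.4%, 1.20e-05), the light harvesting complex 7 of 18 (38.9%, 2.19e-05) and evening clock genes 5 of 9 (55.6%, exact adjusted p = 5.06e-05). Abscisic acid signalling had 5 of 29 (exact adjusted p = 0.019). Morning and day clock genes and flowering time had 3 of 14 each (exact adjusted p = 0.041), and both calls were lost against genes with a symbol of their own (exact adjusted p = 0.075). Jasmonate had 2 of 16, and light signalling had 1 of 25. Chlorophyll synthesis, gibberellin, abscisic acid metabolism, housekeeping and RuBisCO genes had 0. Against genes with a symbol of their own, of which 47.7% had a region in contrast to 36.6% of the rest, 8 of the 12 calls for any region held, while flowering time and chlorophyll synthesis (exact adjusted p = 0.051) and gibberellin and RuBisCO (exact adjusted p = 0.069) missed the threshold.

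Scores were also compared among genes with a region, whose median was 13.7. They were higher for 6 lists. Median scores were 65.7 in starch metabolism, 60.4 in the evening clock genes, 55.0 in cold and dehydration response, 38.8 in flowering time, 28.7 in the light harvesting complex and 26.9 in the morning and day clock genes. The mean percentile among genes with a region was 85.5 for the 9 evening clock genes (permutation test, adjusted p = 0.000533) and 82.4 for the 20 cold and dehydration response genes (adjusted p = 0.00032, from the smallest p that the permutations can give, 2e-05). It was 79.6 for flowering time (permutation adjusted p = 0.00134), 76.8 for starch metabolism (0.0008), 74.7 for the light harvesting complex (0.000533) and 70.0 for the morning and day clock genes (0.040). The call for the morning and day list was lost in each of the 3 other settings, with permutation adjusted p = 0.067 for the region nearest to a gene end, 0.051 with a window of 3000 bp and 0.065 against genes with a symbol of their own. The call for flowering time was lost for the nearest region (0.22).

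The remaining 10 lists did not differ from other genes with a region in score by this test. Median scores were 38.9 over 7 housekeeping genes (mean percentile 69.0, permutation adjusted p = 0.19), 18.7 for jasmonate (0.63), 16.9 for abscisic acid metabolism, 15.5 for chlorophyll synthesis, 15.4 for light signalling and 13.4 for abscisic acid signalling. They were 12.2 for phenylpropanoids and flavonoids, 11.8 for gibberellin, 10.1 for ethylene and 9.39 for RuBisCO. Abscisic acid metabolism passed the test with a window of 3000 bp (permutation adjusted p = 0.013).

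**Figure D3:**
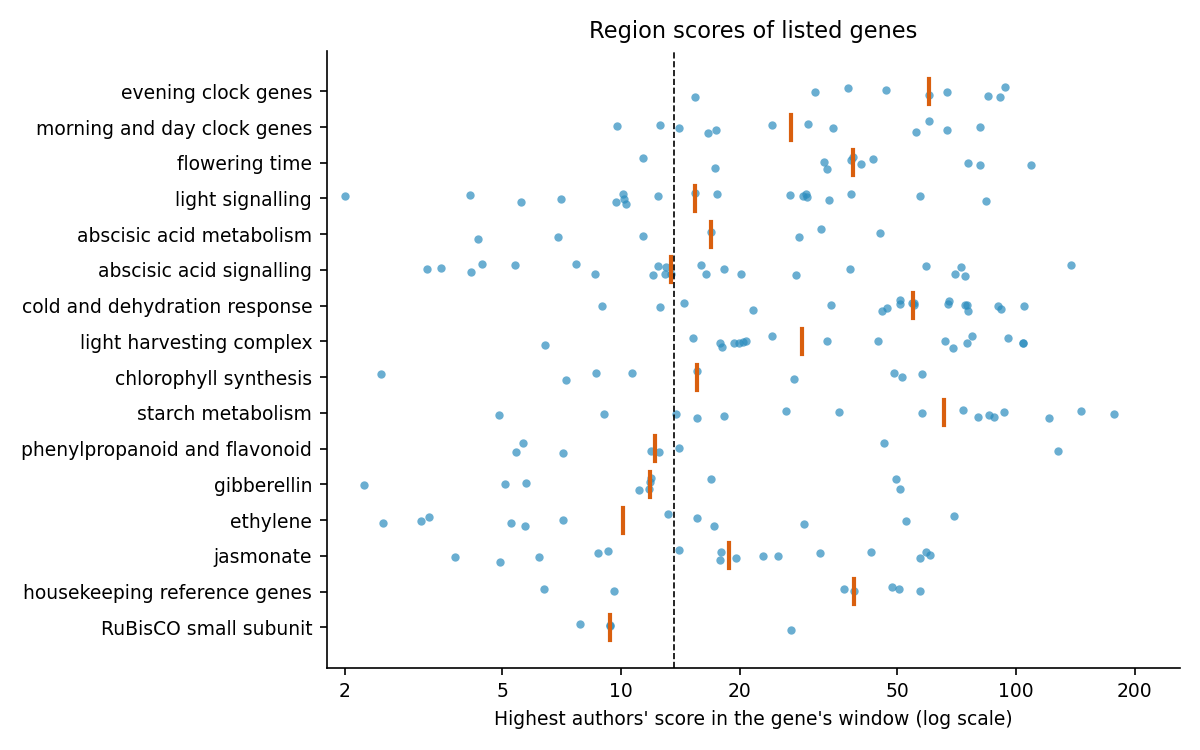
Highest authors' score in the window of each listed gene with a region, on a log scale, by gene list. Blue points are genes (spread vertically for visibility), orange bars list medians and the dashed line the median of 13.7 over all genes with a region; the list medians run from 9.39 for RuBisCO to 65.7 for starch metabolism.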

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

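The backgrounds of named genes and of matched flanks, the counting of shared regions once and the comparison of both clock lists were chosen after the data were seen. Region number, the 3 location classes, the gene-poor bins and the number of lists higher in score kept their direction and call, or stayed within 1.5 times, under every alternative run. The number of lists with more regions than other genes fell from 12 to 7 with the 1000 strongest regions and stayed within 1.5 times under the others. The cause was not tested. Direction reversed, never past the threshold, in these cases. With the 1000 strongest regions 4% of light signalling genes, and 0% of abscisic acid metabolism, chlorophyll synthesis, gibberellin, housekeeping and RuBisCO genes had a region. In the strongest 10% abscisic acid metabolism and RuBisCO had 0%, above the median score RuBisCO had 25%, and with a window of 500 bp ethylene had 33.3%. In percentile of score relative to other genes, the nearest region gave -3.18 for abscisic acid signalling, 3.53 for phenylpropanoids and -2.76 for jasmonate, and a window of 3000 bp gave 6.11 for phenylpropanoids and 3.09 for gibberellin. Of the other single results under alternatives fixed before the data were examined, 376 kept direction and call, 25 moved, 13 lost a call and 10 gained one. Named genes left without a region under an alternative are not in this tally, as for PRR5 with a window of 500 bp. Classes by promoter, UTR, exon and intron and all motif alternatives were not run, for want of strand, exons and sequence in the gene table used here. No paired analysis was possible because each genotype had 1 library, and without read counts no limit from depth was computed.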

Other observations

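The symbol families, the seed and floral organ genes, the width comparison, the comparison of clock with housekeeping and RuBisCO genes and the backgrounds of named or matched genes were chosen after the data were seen. Among 172 families of genes sharing a symbol stem, each tested against other genes with a symbol (two-sided Fisher's exact test), 1 held regions more often. The B-box genes (BBX), regulators of light responses, had 17 of 20 against 47.7% (exact adjusted p = 0.040), with BBX29 at 104, BBX19 at 60.1 and BBX17 at 59.1. This call is close to the threshold. BBX10 and BBX31 both scored 15.5 and appear to share 1 region, and families were not tested with shared regions counted once. The TCP stem, of growth regulators and 1 chaperonin subunit gene, had 6 of 17 genes among the 1000 strongest regions (exact adjusted p = 0.024), while for any region it had 11 of 17 (0.66). Families with fewer regions included the cysteine-rich LCR genes with 11 of 80 (13.8%, exact adjusted p = 3.97e-08), UMAMIT transporters with 10 of 44 (0.040), the GH stem, which mixes GH3 and GH9 genes, with 4 of 26 (0.040), and MYB genes with 40 of 120 (0.048).

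Regions also lay at genes that make no protein. Of 326 microRNA genes 75 had a region in the window (23.0%, 95% interval 18.5 to 28.0), with 132 at MIR156j, 107 at MIR169h, 87.8 at MIR8167c and 87.4 at MIR167c. Whether these regions also lie in windows of protein-coding genes is not given here. The share was 25% for 625 tRNA genes, 34.5% for 3480 long non-coding RNA genes and 3.55% (2.99 to 4.18) for 3917 pseudogenes, against 40.8% for protein-coding genes. These shares were not tested against each other.

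Of the 16 gene lists, 12 carried regions more often than other genes, and longer non-coding flanks do not account for it as a whole, since 11 of the 12 stayed past the threshold against genes matched on non-coding base pairs, all but RuBisCO (permutation adjusted p = 0.053). Nor does the higher share among genes with a symbol, since 8 stayed, and for the other 4 (lowest exact adjusted p = 0.0511) it stays open, with shares of 78.6% in flowering time, 81.8% in chlorophyll synthesis, 76.9% in gibberellin and 100% in RuBisCO against 47.7 to 47.8% of other genes with a symbol; once these were also matched on non-coding base pairs, chlorophyll synthesis passed (permutation adjusted p = 0.042) and flowering time (0.060), gibberellin (0.12) and RuBisCO (0.15) did not. Use of the genes in seedlings remains a candidate explanation, because only 4 of 27 seed and floral organ genes had a region (14.8%, interval 4.19 to 33.7) against 47.9% of other genes with a symbol (Fisher's exact p = 0.000687). The seed genes alone passed (1 of 16, exact p = 0.000608) and the floral genes alone did not (3 of 11, exact p = 0.23), with no test between them. The seed genes SESA1, SESA2, SESA3 and SESA4 have consecutive locus names but were counted as separate genes. The p-values for the seed genes and for the combined list may therefore be too small. Given these counts, part of the region list may mark chromatin accessible in seedlings. Seedlings of both genotypes had the same age and time of collection, so accessible chromatin is expected in both libraries. How far the comparison with lhy-21 removed its signal was not determined. No expression or accessibility data were used, so these counts cannot tell marking of accessible chromatin from LHY binding limited to genes in use. For strength, use in seedlings stays open as an explanation and was not tested. The 23 clock genes and the 14 housekeeping and RuBisCO genes had 8 and 0 members among the 1000 strongest regions and 10 and 3 in the strongest 10%. They had 20 and 6 above the median score and 21 and 11 over all regions, so the clock genes had the larger share in each set. The group of housekeeping and RuBisCO genes was formed after its counts were seen. Its counts are therefore given without a test and do not decide the question.

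Of all centres, 34.8% fell inside genes. Random placement of weak calls is argued against, since the weakest 10% of regions had 34.9% (32.5 to 37.4) of centres inside genes, below the 54.1% of base pairs. Regions at gene ends whose midpoint falls just inside are a candidate explanation for most of them, since 54.9% (53.5 to 56.3) of these centres lay within 200 bp of an end. That leaves 45.1% deeper inside, and no biological explanation was tested.

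Regions at 5 of the 9 evening clock genes were wide for their score: among the 200 regions nearest in score, the region was wider than nearly all at PRR5 (2184 bp, percentile 100), TOC1 (984 bp, 99.0), ELF4 (1537 bp, 99.0), FKF1 (1609 bp, 99.0) and GI (1679 bp, 98.5), but not at LUX (70.1), BOA (69.7), ELF3 (50.7) or PRR3 (19.9). Of the morning and day list, whose mean of 53.2 did not pass the test (permutation adjusted p = 0.77), PRR9 (94.5), PRR7 (94.0), LNK3 (85.6) and RVE7 (80.1) were also wide, and LHY was at 20.4. The mean percentile of the evening list was 78.4 against 50.1 for other genes with a region (permutation p = 0.00174, adjusted over 16 lists 0.028), and 68.1 for cold and dehydration response genes (adjusted p = 0.032). Longer non-coding flanks are argued against as a whole cause, since the difference held against genes matched on non-coding base pairs (permutation p = 0.00256). It also held once regions within 200 bp were merged (permutation p = 0.00404). Merging cannot separate regions that the peak caller had already joined, so fusion of neighbouring regions at these genes stays open. Clusters of sites, or signal at the same sites in the lhy-21 library from a related protein such as CCA1 that the antiserum may also bind, stay open as hypotheses, since neither was tested here.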
